A study of Homo sapiens with 6 samples.

How the data were processed

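RNA was measured by sequencing in 6 libraries of HaCaT keratinocytes that carried a marsupial photolyase for cyclobutane pyrimidine dimers (CPDs). Each library belonged to 1 of 3 groups of 2, per the labels: untreated control, UVC with the photolyase inactive, and UVC with the photolyase activated by white light. The dose was 15 J/m2 at 254 nm, the harvest came 6 h after irradiation and the white light lasted 2 h, per the series description. The labels do not say whether the replicates of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The series title concerns alternative splicing, but the values used here are per gene, and splicing was not analysed here.

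The libraries were made with an Illumina TruSeq kit, per the labels. Reads were aligned with Bowtie to the hg19 build, per the submitters' processing notes, which name no version of the aligner. The counting rule, its use of strand and the gene annotation are not given in the sources used here. For each library the authors deposited, for 19847 Ensembl genes, a whole read count and a corrected RPKM (cRPKM). The deposited RPKM values are the count divided by an effective length of the gene and by the library's total count, as the values themselves show. All 6 libraries lacked values for the same 354 genes, which left 19493. The ratio of the deposited read count to the deposited cRPKM gave the effective length of a gene, which differed by at most 0.183% between libraries over 6664 genes above 5 cRPKM. Reads shared by near-identical genes (such as those for histones, heat shock protein 70 or the lambda interferons) and by overlapping or antisense genes can be divided between them, so the value of a single such gene is uncertain.

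Total counts ran from 57669389 to 70005705 per library. To check the test, counts were simulated from each gene's mean over all libraries and the libraries' own depths (11926 genes, 50 changed at each size). On them the test recovered 58% of 1.25-fold, 88% of 1.5-fold, 96% of 2-fold and 100% of 4-fold changes for UVC against control. It recovered 70, 94, 96 and 100% for active photolyase against UVC, and 74, 96, 98 and 100% for active photolyase against control. The simulation called 14, 11 and 17 unchanged genes in the 3 comparisons. It changed few genes, whereas most were called in the data, so these rates and counts describe the simulated setting only.

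Counts were tested with edgeR 4.0.16 in R 4.3.3, by its quasi-likelihood F test on a fit of 3 group means to all 6 libraries, so that the groups shared an estimate of the spread (3 residual degrees of freedom per gene, and 10.03 prior degrees of freedom). Libraries were scaled by the trimmed mean of M values (TMM), whose factors were 0.886 and 0.884 for control, 1.18 for both UVC libraries, and 0.954 and 0.957 with active photolyase. Genes were tested if they reached 1 cRPKM in at least 2 libraries, which kept 11926. All tests were two-sided, and a gene was called when its p, adjusted over all tested genes by Benjamini and Hochberg, was under 0.05. Standard errors of log2 fold changes were taken from the fold change and the F statistic. Printed levels are the deposited cRPKM divided by the TMM factor, as mean ± SD with n = 2. The common biological coefficient of variation was 4.62%. TMM takes most genes as unchanged, so every change is relative to the bulk of the transcripts and says nothing of total RNA per cell.

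The comparisons, tests, gene lists, named genes and most alternatives were fixed before the data were examined. That plan named limma on log2(cRPKM + 1) as the main test, because only cRPKM values were expected. Since the libraries also held counts, edgeR became the main test, and the planned limma 3.58.1 test is given as an alternative. Named genes were, for each comparison, the 10 with the largest rise and the 10 with the largest fall in log2(cRPKM + 1) among genes called, with a mean of at least 5 cRPKM in the higher group and no overlap between replicates. Also fixed were CDKN1A, MDM2, XPC, DDB2, ERCC6, ATR, CHEK1, FOS, ATF3, BCL2L1 and CASP9 and, for each list, the members of smallest p, up to 2 each way or 4 in a single direction.

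A total of 26 gene lists covered p53 targets, nucleotide excision repair, ATR and checkpoint signalling, immediate-early and AP-1 genes, NF-kB and inflammatory genes, the interferon response, G1/S and DNA replication, G2/M and mitosis, SR proteins and their kinases, hnRNP and PTB proteins, RNA polymerase II subunits and elongation factors, ribosomal proteins, mitochondrially encoded genes, replication-dependent histones, basal keratinocyte genes, keratinocyte differentiation, the unfolded protein and integrated stress response, heat shock, NRF2 and oxidative stress, the circadian clock, cholesterol synthesis, the BCL2 family and caspases, the EGF receptor family and its ligands, and markers of melanocytes, fibroblasts and immune cells. Lists with at least 5 tested members were compared with all other genes by limma's camera with a preset correlation between members of 0.01, adjusted over the lists of a comparison. The camera test with an estimated correlation and fry were alternatives.

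The share of the UVC response left with active photolyase was the covariance, over tested genes, of the change with active photolyase and the change after UVC, both against control, divided by the covariance of UVC changes between libraries. No library stood on both sides of a covariance. On simulated data with a share of 0.3 it gave 0.305. Overlaps of calls between comparisons that share libraries were set beside 20 simulations of unchanged groups and beside the number for independent lists. The genomic span, exon number and transcript GC of genes came from GENCODE 29 gene models on GRCh38, found for 11728 tested genes (98.3%). That build differs from hg19, so no coordinates are given. Rank correlations with span are across genes, which are not independent replicates, and their two-sided p came from 100000 permutations. Symbols were matched by Ensembl identifier: 18913 genes had a current symbol, 28 a GENCODE symbol only, and 552 are shown by identifier. Lists were matched by symbol, so these 552 could enter no list, and a list may be incomplete. Some genes that the naming rule picks are not reported here.

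Alternatives covered pseudocounts of 0.1 and 2 in the limma test, no filter and a filter of 5 cRPKM, median-centring, quantile normalization, other variance models, only the 2 groups compared, the replicate number as a block and each library left out. Added after seeing the data were the limma test as planned, library totals, DESeq2 size factors in edgeR, DESeq2 1.42.0, fry with library totals, genes that fell or rose taken alone, the share left by span, and partial correlations given effective length, GC or exon number. Tables were handled in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9.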

Results

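The cells were HaCaT, an immortalised line of human skin keratinocytes, made to carry the CPD photolyase of the marsupial Potorous tridactylus. UVC light joins neighbouring pyrimidines of DNA into CPDs and other lesions that stall RNA polymerase II, and a CPD photolyase splits CPDs when visible light drives it. The 3 groups of 2 libraries were untreated cells (control), cells given 15 J/m2 of UVC and harvested 6 h later with the photolyase inactive (UVC), and cells given the same dose plus 2 h of white light (UVC with active photolyase). White light was given only in the last group, so that photolyase activation and the light itself go together in every comparison with it. Total gene counts were 70005705 and 69585649 in control, 58420526 and 57669389 after UVC, and 69960028 and 67153025 with active photolyase. Mitochondrially encoded genes took 3.32 and 3.92% of counts in control, 5.13 and 5.28% after UVC, and 4.09 and 3.21% with active photolyase. The replicates of a group correlated at r = 0.998 over log2 cRPKM in each group, against 0.902 to 0.979 between groups. Replicate counts differed by more than sampling noise in each group, with a chi-square per degree of freedom of 24.3 in control, 5.61 after UVC and 15.0 with active photolyase. The first principal component held 84.4% of the variance and placed the active-photolyase libraries (-14.2 and -14.8) between control (-38.8 and -40.6) and UVC (54.6 and 53.7). Markers of other cell types were mostly under the filter. Of melanocyte markers 1 of 7 was tested (MITF, 1.36 ± 0.109 scaled cRPKM in control), of fibroblast markers 2 of 9 (COL1A1 at 5.85 ± 0.793 and DCN at 1.19 ± 0.00584 in control), and of immune cell markers 4 of 11 (CD3E, CD14, CD68 and CD74). MITF fell after UVC by 1.14 on the log2 scale, and of the fibroblast markers 1 rose and 1 was not called. Of the immune cell markers, 2 rose and 1 fell.

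UVC with inactive photolyase was compared with control to ask what the radiation did to transcript levels. Inflammatory cytokine transcripts were among the largest rises of the named genes. TNF (ENSG00000232810) went from 0.847 ± 0.161 to 20.01 ± 1.74 scaled cRPKM (SD, n = 2 each), a log2 fold change of 4.56 ± 0.12 (SE), and the chemokine gene CCL20 went from 13.4 ± 0.631 to 133 ± 0.00593 (3.30 ± 0.08). IFNB1, which encodes interferon beta, rose by 4.12 ± 0.14, from 1.248 ± 0.197 to 21.8 ± 1.88. Among the largest falls, MACC1 (ENSG00000183742) dropped from 122 ± 7.16 to 3.66 ± 0.224 (-5.06 ± 0.07), TGFA, a ligand of the EGF receptor, from 138 ± 2.89 to 4.99 ± 0.169 (-4.79 ± 0.06), and HAS2, a hyaluronan synthase, from 143 ± 3.96 to 5.27 ± 0.605 (-4.76 ± 0.09).

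Further large rises were in the neutrophil-attracting chemokines CXCL2 (3.48 ± 0.13) and CXCL3 (3.47 ± 0.10) and in the lambda interferons IFNL1 (3.06 ± 0.11), IFNL2 (3.84 ± 0.13) and IFNL3 (4.01 ± 0.28), whose near-identical sequences make the value of each uncertain. The IFNL3 value depended on the control library used, at 3.42 without control replicate 1 and 4.998 without control replicate 2. The histone H2B gene H2BC21 rose by 2.95 ± 0.07, from 20.1 ± 0.771 to 155 ± 2.71, and ENSG00000187990, a gene with no symbol here, by 3.10 ± 0.10. Further large falls were PGBD5 (-5.14 ± 0.10), the heparan sulphate sulphotransferase HS3ST2 (-4.64 ± 0.06), LMO7 (-4.56 ± 0.07), TMCC3 (-4.48 ± 0.06), BCAR3 (-4.44 ± 0.06), the complement regulator CD55 (-4.34 ± 0.07) and the interleukin-33 receptor IL1RL1 (-4.25 ± 0.06). Each of these had an adjusted p of at most 1.18e-08 by edgeR.

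Of 11926 genes, edgeR called 5074 higher and 5140 lower, which is 85.6% of those tested, at an adjusted p under 0.05. Changes of at least 2-fold were 1179 rises and 2213 falls, and changes of at least 4-fold were 168 and 596. The split depended on scaling: with library totals, which moved the median change of all genes to 0.42, 7095 rose and 3542 fell, and the balance of 2-fold changes turned to 2805 rises and 1301 falls. Calls were 7084 and 3519 with limma on values as deposited (1635 and 1009 of at least 2-fold), and 6416 and 4024 with median-centring (1061 and 1238).

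Genes of the NF-kB and inflammatory list rose as a group. Of 25 tested, 17 rose and 5 fell, with a median log2 change of 1.18 (camera adjusted p = 5.51e-05, and adjusted p = 0.756 with an estimated correlation). Interleukin 6 (IL6) rose by 2.58 ± 0.06, while NFKB1, which encodes an NF-kB subunit, fell (-3.01 ± 0.05), as did TNFAIP3, an inhibitor of the pathway (-1.80 ± 0.06). Of 22 replication-dependent histone genes, whose mRNAs normally end in a stem-loop, 19 rose and 1 fell (median 1.51, adjusted p = 0.000556, and adjusted p = 0.756 with an estimated correlation). H2BC21 and H2AC25 (2.00 ± 0.08) had the smallest p among the rises, and the call of H4C8 (-0.23 ± 0.09) turned to 0.19 with library totals. Of 81 ribosomal protein genes 72 rose and 2 fell, by small amounts (median 0.34, adjusted p = 0.000654, and adjusted p = 0.953 with an estimated correlation). RPS27 (0.67 ± 0.06) and RPS28 (0.62 ± 0.06) had the smallest p among them, and RPL22L1 fell (-0.89 ± 0.06).

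Of 21 SR proteins and their kinases, which act on splice site choice, 3 rose and 15 fell (median -0.69, adjusted p = 0.00469, and adjusted p = 0.756 with an estimated correlation). TRA2A (-2.05 ± 0.05) and TRA2B (-1.77 ± 0.05) fell, and SRSF11 rose (0.26 ± 0.05). Of 16 heat shock genes 1 rose, HSPB1 (0.63 ± 0.07), and 13 fell, among them the chaperones HSPH1 (-1.88 ± 0.06) and HSPA8 (-1.73 ± 0.06). Their median was -0.83 (adjusted p = 0.0194, and adjusted p = 0.953 with an estimated correlation). In the unfolded protein and integrated stress response list 2 of 20 rose and 16 fell (median -0.79, adjusted p = 0.0131, and adjusted p = 0.756 with an estimated correlation), with HERPUD1 (-1.73 ± 0.05) and the asparagine synthetase ASNS (-1.73 ± 0.05) among the falls. Among basal keratinocyte genes 2 of 15 rose, KRT15 (0.40 ± 0.07) and KRT5 (0.32 ± 0.06), and 12 fell, including the integrin gene ITGB1 (-2.12 ± 0.06). That list had a median of -0.59 (adjusted p = 0.00391, and adjusted p = 0.756 with an estimated correlation). The EGF receptor family and its ligands had the lowest median, -1.61, with 1 rise (ERBB2, 0.65 ± 0.05) and 7 falls among 10 (adjusted p = 0.00247, and adjusted p = 0.756 with an estimated correlation), EREG among them (-2.12 ± 0.05). With a filter of 5 cRPKM the calls of the heat shock list (adjusted p = 0.103) and the unfolded protein list (adjusted p = 0.0882) were lost.

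No list of the DNA damage response was called by camera, which compares members with other genes. By fry, which does not, the direction depended on scaling: the p53 targets (adjusted p = 0.00418) and the BCL2 family and caspases (adjusted p = 0.00614) were called downward with TMM factors and upward with library totals (adjusted p = 0.00218 and 0.01). The nucleotide excision repair, ATR and immediate-early lists were not called by fry with TMM factors (adjusted p = 0.0902, 0.333 and 0.312). With library totals fry called these 3 lists upward (adjusted p = 0.000768, 0.00202 and 0.00407). Of 32 p53 targets 14 rose and 13 fell (median 0.02, adjusted p = 0.937). The cell cycle inhibitor CDKN1A (ENSG00000124762) fell from 683 ± 15.7 to 269 ± 2.03 (-1.34 ± 0.05), MDM2, which marks p53 for degradation, fell (-1.22 ± 0.06), and the pro-apoptotic BBC3 rose (1.39 ± 0.08). For nucleotide excision repair the counts were 15 rises and 12 falls of 34 (median 0.06, adjusted p = 0.679). The damage sensors XPC (0.42 ± 0.07) and DDB2 (0.72 ± 0.06) and the nuclease gene ERCC5 (1.24 ± 0.06) rose, while CDK7 (-3.71 ± 0.08) and ERCC1 (-1.37 ± 0.05) fell. ERCC6, which acts in transcription-coupled repair, fell (-0.52 ± 0.07), a call lost with library totals (-0.10, adjusted p = 0.226) and with limma at pseudocounts of 0.1, 1 and 2 without centring (adjusted p = 0.38, 0.362 and 0.354). In ATR and checkpoint signalling 9 rose and 12 fell of 22 (median -0.26, adjusted p = 0.681). The kinase genes ATR (0.59 ± 0.05) and ATM (1.86 ± 0.06) rose, and CHEK1 (-0.59 ± 0.07) and CDC25A (-1.99 ± 0.08) fell. The immediate-early and AP-1 list split into 15 rises and 13 falls of 31 (median -0.04, adjusted p = 0.681), with FOS up by 2.59 ± 0.06, ATF3 by 1.37 ± 0.06 and the phosphatase gene DUSP10 down (-2.23 ± 0.05). In the BCL2 family and caspases 9 rose and 12 fell of 25 (median -0.08, adjusted p = 0.937). The survival genes MCL1 (-2.19 ± 0.06) and BCL2L1 (-2.06 ± 0.06) and the initiator caspase gene CASP9 (-1.22 ± 0.07) fell.

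Other lists also did not pass the test. They were hnRNP and PTB proteins (3 rises and 19 falls of 24, median -0.43, adjusted p = 0.0783), with PTBP3 at -2.37 ± 0.06, and G2/M and mitosis (18 and 4 of 24, median 0.48, adjusted p = 0.0608), with TOP2A at 1.12 ± 0.06. G1/S and DNA replication had 9 rises and 10 falls of 27 (median -0.05, adjusted p = 0.897), RNA polymerase II subunits and elongation factors 9 and 14 of 28 (median -0.13, adjusted p = 0.208), and keratinocyte differentiation 6 and 12 of 22 (median -0.44, adjusted p = 0.244). The interferon response list had 9 of each among 23 (median -0.11, adjusted p = 0.679), and mitochondrially encoded genes 3 and 4 of 13 (median -0.12, adjusted p = 0.847). NRF2 and oxidative stress had 9 and 5 of 19 (median 0.11, adjusted p = 0.937), the circadian clock 9 and 6 of 16 (median 0.23, adjusted p = 0.937), and cholesterol synthesis 14 and 7 of 22 (median 0.31, adjusted p = 0.937). Within these, the clock gene BMAL1 fell (-3.18 ± 0.07) and BHLHE41 rose (2.31 ± 0.07). With library totals the medians of the ATR (0.16), immediate-early (0.38), interferon (0.30), G1/S (0.37), RNA polymerase II (0.29), mitochondrial (0.30) and BCL2 (0.33) lists turned above 0. For 10 uncalled lists the median, mean and camera direction differed in sign: p53, nucleotide excision repair, ATR, immediate-early, interferon, G1/S, mitochondrial, NRF2, circadian and cholesterol. Adjusted over the list alone, the counts of this comparison changed only for heat shock (14 falls), basal keratinocyte (3 rises), nucleotide excision repair (11 falls) and mitochondrially encoded genes (3 falls).

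**Figure D1:**
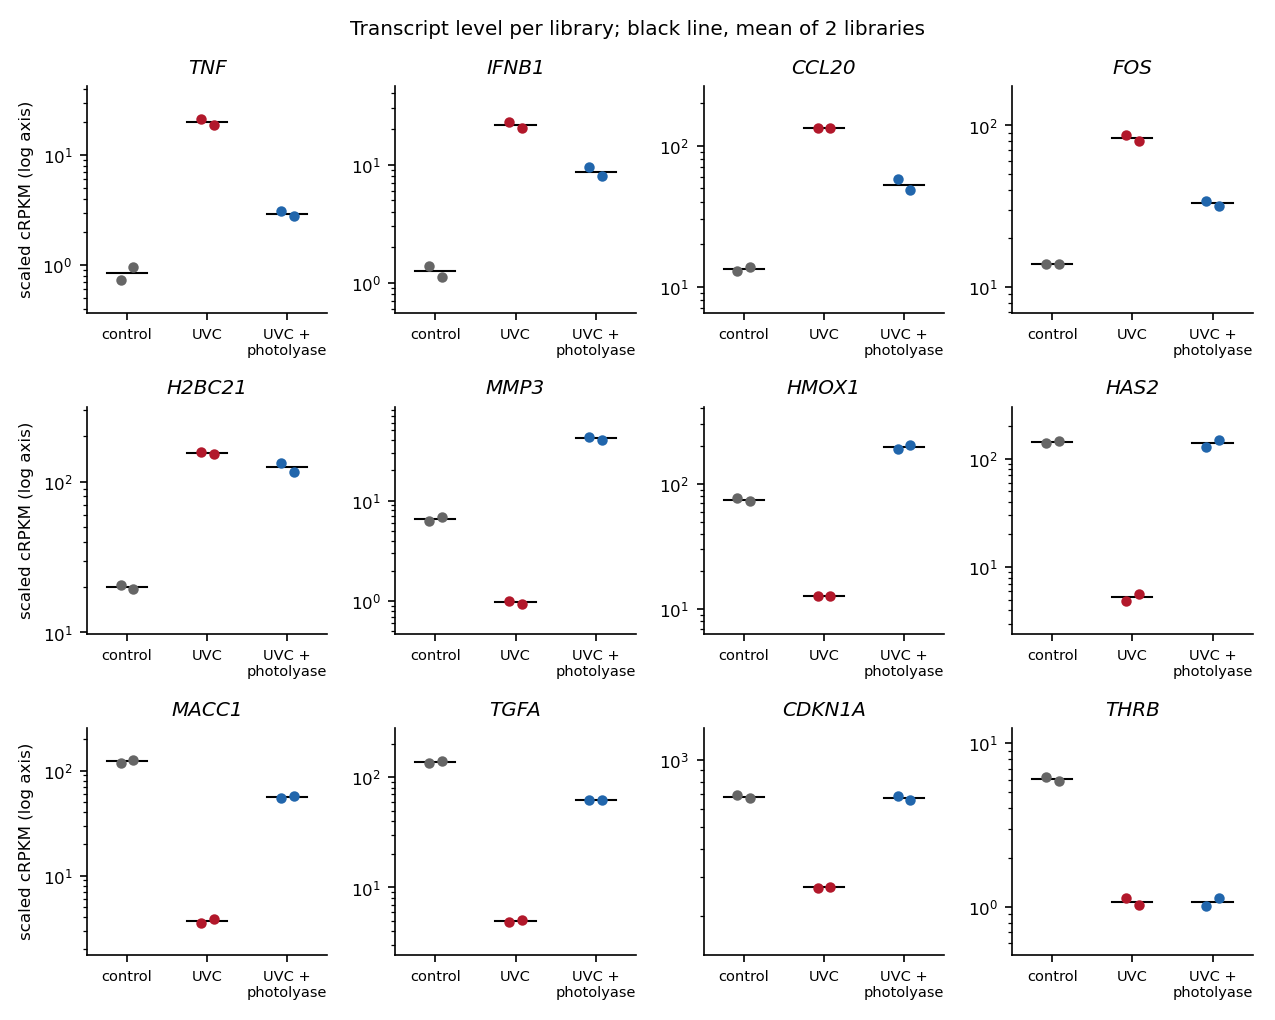
Level of 12 named genes in each library, as scaled cRPKM on a log axis with its own range in each panel. Points are libraries of the control, UVC and UVC with active photolyase groups, and black lines are means of 2. TNF stood at 0.847, 20.01 and 2.92 in the 3 groups, and THRB at 6.04, 1.08 and 1.08.

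UVC with active photolyase was compared with UVC to ask what photolyase activation, together with the white light that drives it, changed. With TMM factors, most transcripts called lower after UVC were higher again (4166 of 5140). That count depended on scaling: with library totals 3542 genes were lower after UVC, and only 3318 of all tested genes were higher here. MMP3, which encodes a matrix metalloproteinase, went from 0.969 ± 0.0428 to 41.7 ± 1.59 scaled cRPKM (SD, n = 2 each), a log2 fold change of 5.43 ± 0.08, and HAS2 from 5.27 ± 0.605 to 139 ± 14.3 (4.72 ± 0.09). The stress genes HSPA6 (4.29 ± 0.12) and HMOX1, heme oxygenase (3.95 ± 0.06), rose from 16.04 ± 0.858 to 313 ± 34.5 and from 12.8 ± 0.119 to 197 ± 11.6. TNF fell back from 20.01 ± 1.74 to 2.92 ± 0.213 (-2.78 ± 0.10).

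BMP6, a growth factor gene, rose by 6.77 ± 0.13 from 0.110 ± 0.000104, and KPNA7 (4.74 ± 0.08), IL13RA2 (4.51 ± 0.09), CD55 (4.34 ± 0.07), MACC1 (3.94 ± 0.07) and TMCC3 (3.90 ± 0.06) were other large rises. Beside TNF, the largest falls by the naming rule, which ranks by log2(cRPKM + 1), included ICAM5 (-2.02 ± 0.10) and ZNG1C (-1.87 ± 0.19), which has near-identical copies and is uncertain. The others were CXCL2 (-1.74 ± 0.10), ID3 (-1.37 ± 0.07), CXCL3 (-1.37 ± 0.08), FOS (-1.34 ± 0.06), CCL20 (-1.32 ± 0.07), CYP1A1 (-1.31 ± 0.07) and CXCL1 (-1.26 ± 0.06). CDKN1A rose by 1.33 ± 0.05 to 676 ± 16.5, and MDM2 (1.07 ± 0.06), CHEK1 (0.85 ± 0.07), BCL2L1 (1.47 ± 0.06) and CASP9 (1.69 ± 0.07) rose as well. XPC (-0.27 ± 0.07), DDB2 (-0.40 ± 0.06) and ATR (-0.20 ± 0.05) fell. Values of ATF3 (0.22 ± 0.06, adjusted p = 0.00273) and ERCC6 (0.22 ± 0.08, adjusted p = 0.0173) turned to -0.09 for both with library totals, and ERCC6 also lost its call when any 1 of the 4 libraries compared was left out (0.18 to 0.23).

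By edgeR, 4676 genes were higher and 4755 lower (79.1% of those tested). There were 1672 rises and 163 falls of at least 2-fold and 410 and 5 of at least 4-fold. With library totals, which moved the median of all genes to -0.34, 3318 rose and 6954 fell, of which 1092 and 807 by at least 2-fold. Limma on values as deposited gave 3309 and 6980 (844 and 201 of at least 2-fold), median-centring 3700 and 6354 (964 and 119), and quantile normalization 3859 and 6116 (996 and 116).

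Heat shock genes rose together: 15 of 16 rose and 1 was not called (median 0.92, camera adjusted p = 1.66e-05, and adjusted p = 0.823 with an estimated correlation), with HSPH1 at 2.23 ± 0.06, HSPA8 at 1.95 ± 0.06 and DNAJA1 at 1.85 ± 0.07. In keratinocyte differentiation 14 rose and 3 fell of 22 (median 0.77, adjusted p = 0.0143, and adjusted p = 0.823 with an estimated correlation), led by the transcription factor gene GRHL3 (2.73 ± 0.06) and the cornified envelope gene SPRR2A (2.09 ± 0.07). Of 24 hnRNP and PTB proteins 20 rose and 1, HNRNPUL2, fell (median 0.59, adjusted p = 0.0143, and adjusted p = 0.823 with an estimated correlation). PTBP3 rose by 1.70 ± 0.05 and SYNCRIP by 1.44 ± 0.05. The unfolded protein and integrated stress response list had 16 rises and 3 falls (median 0.63, adjusted p = 0.0143, and adjusted p = 0.823 with an estimated correlation), with SESN2 at 2.09 ± 0.06. The EGF receptor family and its ligands had 6 rises and 2 falls of 10 (median 0.88, adjusted p = 0.0143, and adjusted p = 0.823 with an estimated correlation). TGFA (3.63 ± 0.06) and EREG (1.74 ± 0.05) rose, and ERBB2 fell (-0.78 ± 0.05). NF-kB and inflammatory genes fell, with 6 rises and 16 falls of 25 (median -0.31, adjusted p = 0.0318, and adjusted p = 0.823 with an estimated correlation), although NFKB1 rose (1.71 ± 0.05) as did IL36G (1.47 ± 0.06). The NF-kB call was lost in each of the limma alternatives (adjusted p = 0.0923 to 0.219), where the median was lower, at -0.52 to -0.61. The hnRNP (adjusted p = 0.051) and unfolded protein (adjusted p = 0.0792) calls were lost with a filter of 5 cRPKM, and the EGF call with median-centring (adjusted p = 0.0687) or quantile normalization (adjusted p = 0.0842).

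SR proteins and their kinases (14 rises and 3 falls of 21, median 0.47, adjusted p = 0.0681), the interferon response (17 and 1 of 23, median 0.69, adjusted p = 0.103) and basal keratinocyte genes (9 and 3 of 15, median 0.52, adjusted p = 0.116) did not pass. With the replicate number as a block the interferon list passed (adjusted p = 0.0179). Nor did p53 targets (14 and 12 of 32, adjusted p = 0.691), nucleotide excision repair (10 and 16 of 34, adjusted p = 0.285) or ATR and checkpoint signalling (12 and 10 of 22, adjusted p = 0.729). CDK7 (3.02 ± 0.07), CDC25A (2.04 ± 0.08), the checkpoint kinase gene WEE1 (1.44 ± 0.05) and the stem-loop binding protein gene SLBP (1.66 ± 0.05) rose in those lists and in the G1/S list (15 and 5 of 27, adjusted p = 0.512). Replication-dependent histones had 9 rises and 9 falls of 22 (median -0.27, adjusted p = 0.916), and ribosomal proteins 7 and 3 of 81 (median -0.01, adjusted p = 0.244). The median and mean differed in sign for the uncalled p53, ribosomal and cholesterol synthesis lists. Adjusted over the list alone, counts of this comparison changed for ribosomal proteins (5 and 1), mitochondrially encoded genes (0 falls in place of 3) and heat shock (1 fall).

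UVC with active photolyase was compared with control to ask what remained of the response. The histone and inflammatory lists stayed high by camera, calls that were lost with an estimated correlation (adjusted p = 0.372 for both). Among named genes with a known span, the largest falls were in genes of long span. H2BC21 was at 125 ± 11.1 scaled cRPKM against 20.1 ± 0.771 in control (SD, n = 2 each), a log2 fold change of 2.64 ± 0.07, and MMP3 stood above control by 2.67 ± 0.07. THRB, the thyroid hormone receptor beta gene with a span of 378.6 kb, was at 1.08 ± 0.0866 against 6.04 ± 0.221 (-2.49 ± 0.08) and was not called against UVC (-0.00 ± 0.08, adjusted p = 0.971), but was called lower than after UVC with library totals (-0.31, adjusted p = 0.00341). HAS2 (-0.04 ± 0.08, adjusted p = 0.674), CD55 (-0.00 ± 0.06, adjusted p = 0.992) and CDKN1A (-0.01 ± 0.05, adjusted p = 0.822) were not called against control, although CDKN1A was called lower with quantile normalization (-0.15, adjusted p = 0.0165).

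Other large rises were ENSG00000197846 (3.58 ± 0.15), KRTAP3-2 (3.45 ± 0.20), ENSG00000187990 (3.31 ± 0.10), IFNL3 (3.01 ± 0.32, at 2.42 without control replicate 1 and 3.995 without control replicate 2), ENSG00000168274 (2.93 ± 0.11), H2BC4 (2.81 ± 0.09), IFNL2 (2.59 ± 0.14) and the late cornified envelope gene LCE3D (2.47 ± 0.13). Whether the genes given by identifier belong to one of the lists was not determined. The largest falls by the naming rule, which ranks by log2(cRPKM + 1), included NAV2 (-2.34 ± 0.11), ENSG00000133808 (-2.23 ± 0.09) and the histone deacetylase gene HDAC9 (-2.01 ± 0.07). With THRB, the others were CLMN (-1.85 ± 0.06), OSBPL10 (-1.79 ± 0.05), FNDC3B (-1.78 ± 0.05), PTPRK (-1.64 ± 0.07), HS3ST2 (-1.64 ± 0.05) and the myosin gene MYO1E (-1.60 ± 0.05). The 9 with a known span, THRB included, covered 102.2 to 915.5 kb. Of the fixed genes ATF3 (1.59 ± 0.06), FOS (1.251 ± 0.06), CASP9 (0.47 ± 0.07), ATR (0.40 ± 0.05), DDB2 (0.32 ± 0.06) and CHEK1 (0.26 ± 0.07) were above control, and BCL2L1 (-0.60 ± 0.05) and ERCC6 (-0.30 ± 0.07) below it. The CHEK1 call was lost without photolyase replicate 2 (0.17, adjusted p = 0.067) and the ERCC6 call with limma at pseudocounts of 0.1, 1 and 2 without centring (adjusted p = 0.133, 0.124 and 0.12). XPC was at 0.15 ± 0.07 (adjusted p = 0.0792), and passed with library totals (0.26, adjusted p = 0.0051). MDM2 was at -0.14 ± 0.06 (adjusted p = 0.0352), a call lost with library totals (-0.03, adjusted p = 0.606) and without control replicate 2 or either photolyase library (adjusted p = 0.143, 0.119 and 0.121).

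By edgeR, 3933 genes were above control and 3919 below (65.8% of those tested), with 484 rises and 241 falls of at least 2-fold. With library totals, which moved the median of all genes to 0.12, 5237 rose and 2840 fell, and limma on values as deposited gave 5114 and 2752.

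Of 22 replication-dependent histones 19 were higher and 3 not called (median 1.86, camera adjusted p = 1.32e-15, and adjusted p = 0.372 with an estimated correlation), with H2AC25 at 1.89 ± 0.08 and H2AC11 at 1.75 ± 0.08. NF-kB and inflammatory genes had 18 rises and 6 falls of 25 (median 0.84, adjusted p = 2.24e-08, and adjusted p = 0.372 with an estimated correlation). IL6 (1.60 ± 0.06) and CCL20 (1.98 ± 0.08) stayed above control and NFKB1 below it (-1.30 ± 0.05). In the interferon response list 20 of 23 rose and 1 fell (median 0.73, adjusted p = 8.73e-07, and adjusted p = 0.698 with an estimated correlation). The antiviral genes IFIT2 (1.39 ± 0.09) and OAS1 (0.86 ± 0.06) rose, and the RNA sensor gene RIGI fell (-0.45 ± 0.09). Ribosomal proteins had 77 rises and 1 fall of 81 (median 0.34, adjusted p = 3.82e-08, and adjusted p = 0.698 with an estimated correlation). Immediate-early and AP-1 genes had 16 rises and 5 falls of 31 (median 0.17, adjusted p = 0.000164, and adjusted p = 0.698 with an estimated correlation), with FOSB at 1.31 ± 0.05. Basal keratinocyte genes had 12 falls among 15, with 3 not called (median -0.47, adjusted p = 0.00019, and adjusted p = 0.372 with an estimated correlation), among them ITGB1 (-0.97 ± 0.06) and the laminin gene LAMA3 (-1.12 ± 0.07). SR proteins and their kinases had 2 rises, the kinases CLK1 (0.97 ± 0.07) and CLK3 (0.57 ± 0.05), and 14 falls, SRSF3 (-0.77 ± 0.05) and SRSF6 (-0.79 ± 0.05) among them (median -0.33, adjusted p = 0.00659, and adjusted p = 0.698 with an estimated correlation). The EGF receptor family had 8 falls of 10, with 2 not called (median -0.32, adjusted p = 0.00878, and adjusted p = 0.372 with an estimated correlation), with TGFA at -1.16 ± 0.05 and EGFR at -0.95 ± 0.06.

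Smaller calls were those of heat shock (13 rises and 1 fall of 16, median 0.33, adjusted p = 0.0124, and adjusted p = 0.698 with an estimated correlation), with HSPE1 at 0.45 ± 0.05, and keratinocyte differentiation (12 and 3 of 22, median 0.34, adjusted p = 0.0404, and adjusted p = 0.698 with an estimated correlation), with SPRR2A at 0.81 ± 0.07. The ATR and checkpoint list (11 and 2 of 22, median 0.20, adjusted p = 0.0415, and adjusted p = 0.698 with an estimated correlation) and the G1/S list (17 and 2 of 27, median 0.21, adjusted p = 0.0415, and adjusted p = 0.756 with an estimated correlation) had ATM at 1.35 ± 0.06 and PCNA, the replication clamp, at 0.54 ± 0.05. Each of these 4 calls was lost when certain single libraries were left out. Heat shock lost its call without photolyase replicate 2 (adjusted p = 0.0573), keratinocyte differentiation without control replicate 2 (0.0816) or photolyase replicate 1 (0.0562), the ATR list without control replicate 1 (0.0852) or photolyase replicate 2 (0.0743), and G1/S without control replicate 1 (0.051), control replicate 2 (0.0548) or photolyase replicate 2 (0.208). The ATR call was also lost with no filter (0.0537), with a filter of 5 cRPKM (0.126) and with limma at pseudocounts of 0.1, 1 and 2 (0.0515 to 0.0548), and the differentiation call with a robust variance model (0.052) and limma at pseudocount 0.1 (0.0629). Among lists not called were p53 targets (13 and 9 of 32, adjusted p = 0.379), nucleotide excision repair (9 and 13 of 34, adjusted p = 0.678), hnRNP and PTB proteins (12 and 6 of 24, adjusted p = 0.577) and NRF2 and oxidative stress (9 and 2 of 19, adjusted p = 0.0527), which passed with the replicate number as a block (adjusted p = 0.042). In this comparison the counts adjusted over the list alone differed for histones (20 rises), SR proteins (15 falls), NRF2 (8 rises) and the circadian clock (9 rises in place of 8).

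**Figure D2:**
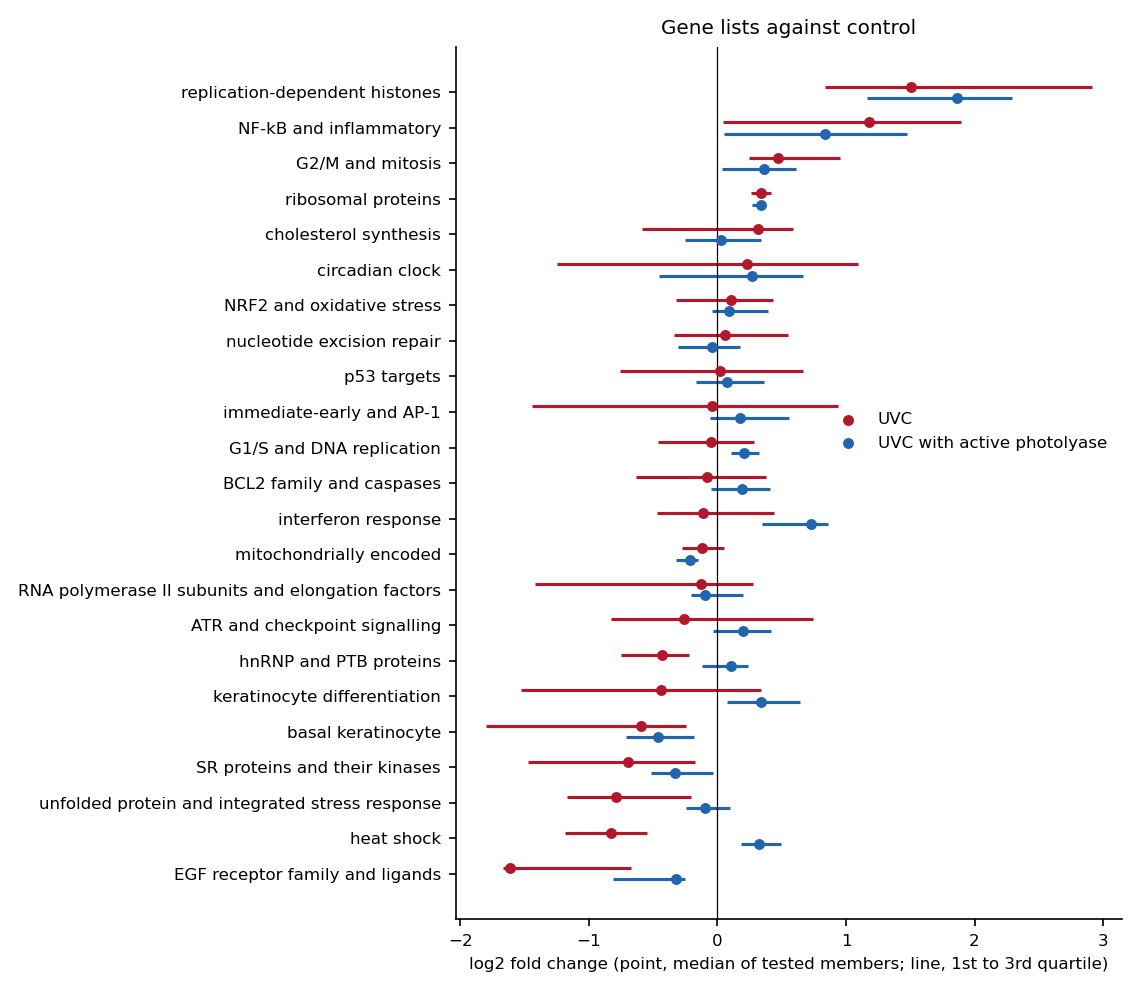
Median log2 fold change of each tested gene list against control, with lines from the 1st to the 3rd quartile of its members, after UVC and after UVC with active photolyase. Histones lay at 1.51 and 1.86, and the EGF receptor family at -1.61 and -0.32.

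How much of the UVC response was left with active photolyase was measured over all 11926 tested genes. The share left was 29.4%, from 28.4 to 30.2% over the choices of libraries. For genes that fell after UVC the mean log2 change against control went from -1.07 to -0.26, and for genes that rose from 0.77 to 0.36. The covariance measure gave 17.7% within the fallen genes alone and 58.3% within the risen genes. Within such a subset it follows differences between genes, so it is not the part of their mean change that was left. Of the 5140 fallen genes 4166 (81.1%) rose again against UVC: HAS2 was among the 1220 of these not called against control, MACC1 among the 2300 still below it and MMP3 among the 646 past it. Of the 5074 risen genes 3987 (78.6%) fell again, with 2104 still above control, 1630 not called against it and 253 past it. Together 8153 genes moved back, against 4038 for independent lists. At most 1 did in 20 simulations of unchanged groups, which says little because they call few genes. Both comparisons use the same UVC libraries, so part of the excess may come from them. In the same direction again, 219 genes fell and 183 rose. All these counts rest on TMM factors. With library totals 3542 genes fell after UVC and 3318 rose against UVC, fewer than the 4166 above.

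**Figure D3:**
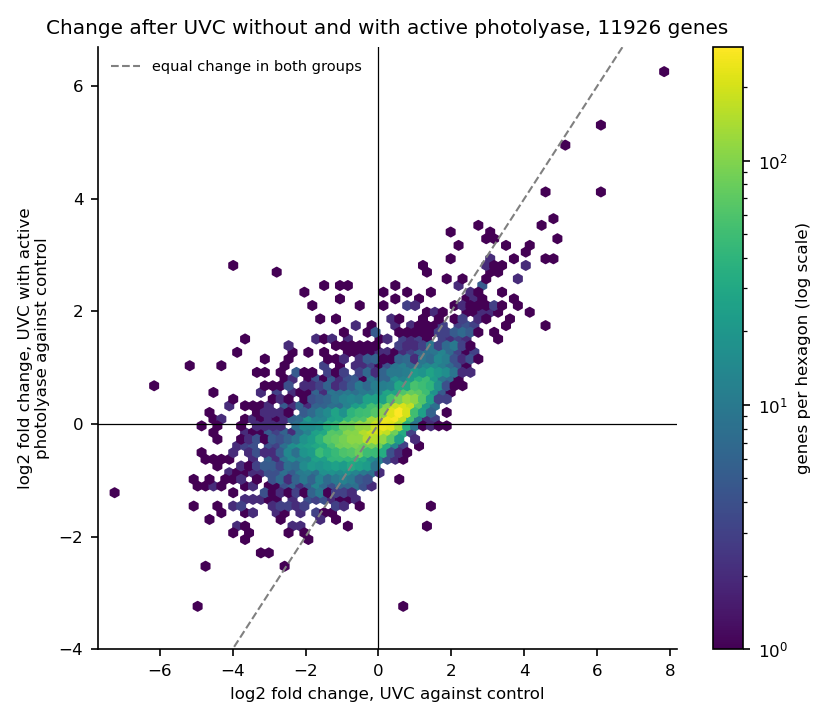
Log2 fold change against control after UVC (horizontal) and after UVC with active photolyase (vertical) for 11926 genes, coloured by the number of genes per hexagon on a log scale. The dashed line marks equal changes, and the share of the UVC change left was 29.4%.

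UV lesions fall on a gene in proportion to its length, so the change of each gene was set against its genomic span. With genes split by span into 5 equal bins, medians were highest in the shortest bin and lowest in the longest for both comparisons with control. In the shortest bin (median 5.16 kb) the median log2 change was 0.39 after UVC and 0.25 with active photolyase, both against control, and in the longest bin (median 146.6 kb) it was -0.23 and -0.30. With library totals these became 0.81 and 0.36 in the shortest bin and 0.19 and -0.19 in the longest, so the direction in the longest bin after UVC depended on scaling. Falls of at least 2-fold with active photolyase made up 8.7% of the longest bin, HDAC9 and NAV2 among them, and 0.1% of the shortest. Across 11728 genes the rank correlation of span and change was -0.243 for UVC against control and -0.438 for active photolyase against control (permutation p = 1e-05, the smallest that 100000 permutations can give, adjusted over 3 comparisons 1.5e-05). Given effective mRNA length these were -0.123 and -0.334, and given transcript GC -0.165 and -0.393. For active photolyase against UVC it was 0.025 (permutation p = 0.008, adjusted p = 0.008), with weaker values without UVC replicate 1 (0.010) and without photolyase replicate 2 (0.012), and it turned to -0.058 given effective mRNA length and -0.054 given transcript GC.

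Among 2191 genes at least 2-fold lower after UVC, the part of the fall left with active photolyase was larger in longer genes. Its median was 9.9, 16.5, 19.8, 28.3 and 43.3% in 5 bins with median spans of 11.96, 28.4, 48.5, 86.3 and 171.3 kb. The rank correlation across these genes was 0.445 (permutation p = 1e-05, the smallest possible, adjusted over 2 tests 2e-05), and 0.404 to 0.486 over 8 combinations of libraries. HDAC9, with a span of 915.5 kb, went from -3.61 ± 0.08 after UVC to -2.01 ± 0.07, while HAS2, with 29.3 kb, went from -4.76 ± 0.09 to -0.04 ± 0.08. Among 1138 genes at least 2-fold higher after UVC the medians were 56.6, 52.1, 47.6, 49.5 and 52.6% (rank correlation -0.11, permutation p = 0.0002, adjusted p = 0.0002). This split by span was chosen after the length correlations had been seen.

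**Figure D4:**
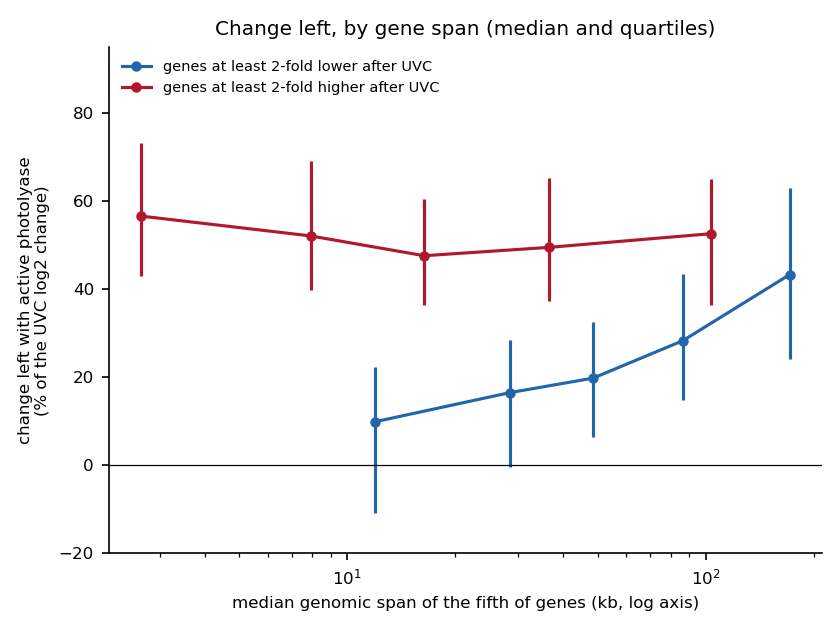
Change left with active photolyase, as a percent of the log2 change after UVC, against the median genomic span of each of 5 bins of genes (log axis), for genes at least 2-fold lower or higher after UVC. Points are medians and lines run from the 1st to the 3rd quartile, and in the lowered genes the medians rose from 9.9 to 43.3%.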

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

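Tests chosen after the result was seen were those with library totals, DESeq2, DESeq2 size factors, the planned limma test beside edgeR, fry with library totals, fallen or risen genes alone, the share left by span, and partial correlations given effective mRNA length, GC or exon number. Counts of all calls stayed within 1.5 times under 20 alternatives: for UVC against control 3955 to 7095 higher and 3517 to 6109 lower, for active photolyase against UVC 3302 to 5476 and 3981 to 6987, and against control 3002 to 5237 and 2725 to 4508. Counts of 2-fold changes moved more. For UVC against control they ran from 743 (filter of 5 cRPKM) to 2805 (library totals) higher and from 826 (limma with pseudocount 2) to 2881 (no filter) lower. For active photolyase against UVC they were 677 to 2285 higher and 110 to 807 lower (1066 and 691 with limma at pseudocount 0.1), and against control 149 to 1034 higher and 71 to 373 lower, with the lowest from limma with pseudocount 2, which shrinks folds of low genes. DESeq2 gave 4827 and 5047, 4535 and 4366, and 3507 and 3664 calls.

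Without each library in turn, calls of UVC against control ranged from 4710 to 5247 higher and 4870 to 5121 lower, of active photolyase against UVC from 4291 to 4764 and 4177 to 4939, and against control from 3259 to 3731 and 3367 to 3830. The lone library of a group was then assumed to vary like the others. The genes that moved back numbered 7357 to 8229, and the length correlations ranged from -0.253 to -0.23, 0.01 to 0.04 and -0.457 to -0.407. The correlation for active photolyase against UVC was weaker without UVC replicate 1 (0.01) or photolyase replicate 2 (0.012) and reversed given effective mRNA length (-0.058) or GC (-0.054). The share of the response left was 31.6% with pseudocount 0.1, 28.4% with a filter of 5 cRPKM and 28.3% with quantile normalization. The covariance measure gave 17.7% within fallen and 58.3% within risen genes.

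Single genes that reversed had small changes. With limma at pseudocounts of 0.1, 2 and 1 and with library totals, MT-ND3 after UVC was at 0.0867, 0.0867, 0.0867 and 0.089, H4C8 at 0.182, 0.165, 0.173 and 0.187 (median-centred 0.0453, quantile 0.0255), and for active photolyase against UVC ERCC6 was at -0.084, -0.0419, -0.0569 and -0.089 and ATF3 at -0.0857, -0.0849, -0.0853 and -0.0856 (quantile -0.106). By fry the p53 targets (median 0.0204, mean -0.16) and cholesterol synthesis (0.31, mean -0.10) were called downward after UVC and histones (-0.27) upward between the irradiated groups. With library totals fry called both lists upward (means 0.258 and 0.318) and gave no call for the histones (adjusted p = 0.587), so these directions rest on scaling. The single genes above also turned with library totals, where the edgeR test was the same and only the scaling changed. Their directions therefore rest on scaling too. Of single genes over all alternatives, 6642 values kept direction and call, 19 reversed, 125 lost and 18 gained a call. Of list tests 1352 kept theirs, 3 reversed, 52 lost and 111 gained one. Every list call by camera was lost with an estimated correlation, where the lowest adjusted p of a called list was 0.372.

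Replicate numbers showed little sign of pairing with control: deviations from group means correlated at -0.019 (control and UVC) and 0.046 (control and photolyase). Between both irradiated groups the correlation was 0.181, and whether libraries were paired is not settled by these values. The replicate number as a block gave 5086 and 5152, 4690 and 4790, and 3981 and 3956 calls. MT-CO1 (-0.29 between the irradiated groups, adjusted p = 0.0519) lost its call and the interferon and NRF2 lists gained theirs, with no other change among the named genes and lists. The smallest simulated changes were recovered in 58 to 74% of simulated cases.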

Other observations

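Tests of gene families, of the share left by span, of exon number, S phase, SLBP, overshoot and white light were chosen after the results were seen. Grouped by symbol, 107 families of at least 12 tested genes were compared with all other genes in each comparison by camera. Matrix metalloproteinases, which cut the extracellular matrix, had the smallest p for active photolyase against control: 11 of 14 rose and 1, MMP14 (-0.42 ± 0.05), fell (median 0.54, adjusted p = 3.89e-07, and adjusted p = 0.777 with an estimated correlation). MMP3 (2.67 ± 0.07), MMP10 (1.88 ± 0.06), MMP9 (1.57 ± 0.06) and MMP1 (1.16 ± 0.06) rose most along with MMP24 (1.17 ± 0.09). The spans of MMP3, MMP10, MMP9 and MMP1 were 7.65 to 10.1 kb, and short genes rose in general with active photolyase (median 0.25 in the shortest bin). After UVC alone MMP3 (-2.76 ± 0.09), MMP10 (-1.61 ± 0.06) and MMP1 (-1.03 ± 0.06) were below control. Others, such as MMP25 (1.36 ± 0.16) and MMP24 (1.31 ± 0.08), were above it, so the family was split after UVC. Claudins, proteins of tight junctions, had 11 rises among 12, with 1 not called (median 0.57, adjusted p = 0.00146, and adjusted p = 0.777 with an estimated correlation). CLDN23 was at 1.63 ± 0.07 and CLDN3 at 1.24 ± 0.13. After UVC alone both were also above control (2.16 ± 0.07 and 1.20 ± 0.13), while others, such as CLDN1 (-1.15 ± 0.05), were below it.

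Some families with long genes stood below control with active photolyase, of which only 2 are given here, and others, such as PIK (median span 89.04 kb, median 0.063, adjusted p = 0.965), were not called. Protein tyrosine phosphatases of the PTPN group (median span 102.8 kb) had 9 falls and 1 rise among 13 (median -0.65, adjusted p = 0.000252, and adjusted p = 0.777 with an estimated correlation), with PTPN13 at -1.15 ± 0.05. Myosins (175.3 kb) had 10 falls and 4 rises among 14 (median -0.54, adjusted p = 0.00347, and adjusted p = 0.992 with an estimated correlation). Library totals did not turn the median of the metalloproteinase, claudin, PTPN or myosin family.

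The part of the UVC fall left with active photolyase was larger in longer genes (rank correlation 0.445 across 2191 genes). Transcript GC, mature mRNA length, and expression level with the depth of the UVC fall were each held constant, and the correlation stayed at 0.443, 0.403 and 0.49, so none of them accounts for it alone. Given exon number, which goes with span, it was 0.331. With GC, mRNA length, level and UVC fall held constant together it was 0.448, and with library totals 0.465. A slower return of transcripts of longer genes may explain it, but this stays an untested hypothesis: the value of 0.448 only restates the pattern, and no return rate was measured. RNA half-life and the choice of isoforms were not tested.

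Replication-dependent histone transcripts stood above control in both irradiated groups (medians 1.51 and 1.86). Short genes rose in general, but the histone medians lay at percentile 100 of 10000 lists of genes from the same bins of span and level in both comparisons. The medians of those lists were 0.48 and 0.31, which argues against length as the whole cause as far as the bins match it. Histones had a median span of 0.82 kb and may be shorter than most genes of their bin. Exon number was not matched, and histones were not left out of the bins. Those lists did not match the correlation between histone genes (estimated at 0.21 and 0.23), so the percentile overstates the certainty. More cells in S phase cannot be told apart from other causes: the G1/S list had a median of -0.046 after UVC, which library totals turned to 0.37, and 0.21 with active photolyase. SLBP, whose protein binds the histone stem-loop, fell after UVC (-1.48 ± 0.05) but was above control with active photolyase (0.18 ± 0.05, adjusted p = 0.0058), so a low SLBP transcript level at harvest could account at most for the UVC group. Polyadenylated histone transcripts were not told apart from others here, and reads shared by histone copies could move single genes.

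With active photolyase 101 genes were at least 2-fold above both control and UVC, while 1 gene, ENSG00000214899, was below both. Independent lists would give 67.9, a number that leaves out that both comparisons share the photolyase libraries. Simulations of unchanged groups gave 0, which says little because they call few genes of any size. MMP3, LCE3D, the BMP antagonist gene GREM1 (2.33 against control), RNASE7 (1.81), HMOX1 (1.40), CXCR4 (1.38) and IFIT2 (1.39) were among them. CXCR4 was near the filter, at a mean deposited cRPKM of 0.415 in control, 0.395 after UVC and 1.155 with active photolyase. It passed the filter of 1 cRPKM only through the photolyase libraries, as did others of the 101, such as OPRL1 and KIAA1755. With library totals 97 genes were above both and 5 below, which argues against scaling as the source. An overshoot of transcripts lowered by UVC may hold for the 53 called lower after UVC, such as MMP3. These calls rest on TMM factors: BMP2, called lower after UVC at -0.19, went from 19.955 to 23.37 in mean deposited cRPKM. By definition such an overshoot does not cover the 15 called higher after UVC, and it stays open for the 33 with no call. White light itself cannot be told apart from CPD removal for any of the 101, because no library had white light without UVC.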
